A study of Homo sapiens with 5 samples.

How the data were processed

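The series holds poly(A) RNA sequencing of A549 cells, an established human lung carcinoma epithelial line. Per the labels' protocols, cells were transfected with 1 µg/mL poly-IC by Lipofectamine 2000 and harvested 0.5, 1, 2 or 4 h later, and 10 ng of Drosophila total RNA was added to the RNA of each sample before oligo-dT selection. The mock sample received the transfection reagent alone for 4 h. Libraries were sequenced on an Illumina HiSeq 2000, per the labels. Each of the 5 conditions has 1 library. TopHat2, HTSeq and the hg19 build are named per the submitters' processing notes; their versions, the annotation and the strand setting are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene can therefore not be told apart.

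The authors deposited 1 table for the whole series, with 13864 gene rows and 1 row without a name, which repeats the hours and was left out. The columns of the 1, 2 and 4 h libraries hold whole counts as deposited, with no normalization seen in the values; a factor under 1 followed by rounding cannot be excluded. The columns of the mock and 0.5 h libraries hold another deposited signal. In all 13864 rows of both (100%), the value is 4 times a whole number plus 2. That whole number was taken as the read count, which the form of the values allows but does not prove. Why the authors deposited these columns in that form is not stated. Whether they carry a scaling relative to the other columns is not stated either, so results from the values as deposited, with no scaling at all, are given beside the main ones. The highest value in every row as deposited is at least 32. The table holds 0 rows with Drosophila names, so scaling to the added RNA was not used here. The 22 rows named by a spreadsheet date number and the 23 rows that share 11 symbols were kept in the fits and are not named. Symbols are those of the table.

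The recovered totals were 30015691 reads in the mock library, and 27802868, 22832097, 13868501 and 13007527 at 0.5, 1, 2 and 4 h. Libraries were scaled with edgeR's TMM factors, which were 0.985 for the mock and 1.06, 1.13, 1.04 and 0.818 in order of time. TMM sets the typical gene as unchanged, so a ratio to mock says how a gene moved relative to the other genes, not per cell. The choices in this and the next paragraph were fixed before the data were examined, except where stated.

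Each poly-IC library was compared with the mock library by the ratio of scaled counts, with a 95% exact Clopper-Pearson interval from the binomial share of the 2 counts. The interval and the floor of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules. A gene was counted as higher or lower when its whole interval lay beyond 2-fold and it had at least 20 reads in 1 of the 2 libraries. Such a comparison is between 2 libraries, has no replicate check and gives no p-value. Log2 ratios use a prior count of 0.5. A ratio to a mock library at 0 reads is given as "at least", against 3 counts in that library, and for genes at 0 reads after poly-IC only the reads are given, apart from gene list medians and flagged genes, where the log2 value rests on the prior count. The trend with hours (0, 0.5, 1, 2 and 4) over the 5 libraries was tested with edgeR's quasi-likelihood test (glmQLFit, glmQLFTest) and Benjamini-Hochberg adjustment at 0.05, on 13585 genes with at least 20 reads in 1 library. It has 3 residual degrees of freedom, and any departure from a straight line on the log scale counts as error. The common dispersion was 0.118, a coefficient of variation of 34.3%. The design assumed counts in every column, and the test was run on the recovered reads where the deposited columns held the other unit.

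The 28 gene lists cover interferon genes, interferon-stimulated genes, NF-kB and inflammatory targets, immediate early genes, the integrated stress response, chaperones of the endoplasmic reticulum, heat shock, p53 targets, housekeeping genes, cytosolic and mitochondrial ribosomal proteins, nuclear-encoded oxidative phosphorylation subunits, mitochondrially encoded genes, replication histones, proteasome subunits, translation factors, cell cycle genes, NRF2 targets, epithelial markers of the line, snoRNA host genes, nuclear long non-coding RNAs, KRAB zinc fingers, double-stranded RNA sensing, RNA decay machinery, and markers of immune, fibroblast, endothelial and erythroid cells. For a list the median log2 ratio is given with its percentile among 10000 random lists of the same size drawn from 20 bins of mean expression, as a description of these libraries, and, where members were at 0 reads, again with those at their bound. Spreads of medians come from 2000 bootstrap draws of members. Named genes are the 12 with the highest and 12 with the lowest interval bound at 4 h, the 5 of each at the other times, up to 4 members per list with the largest log2 ratio in size at 4 h, the 5 rising and 5 falling genes with the smallest adjusted p of the trend, and IFNB1, IFNL1, IFNL2, IFNL3, OAS1, OAS2, OAS3, GAPDH, ACTB and EEF1A1. The rule also named 1 gene that is not reported here. A gene named outside this rule is said to be so.

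Alternatives fixed in advance were total-count and DESeq2 scaling, other count filters, the point estimate in place of the interval, a prior count of 5, the 0.5 h library as reference, DESeq2 and limma-voom for the trend, the rank of the time point, and leaving out each library in turn. Added after the data were seen were the values as deposited, counts divided by 10, limma-trend, total-count scaling of the trend, and ratios adjusted for GC content in 20 bins. GC content, length and neighbours of genes came from GENCODE release 29, of another genome build than hg19 and used for sequence, order and distance only; 12602 genes (90.9%) had a sequence. The steps were tested on simulated data. Among 200 genes changed with a dispersion of 0.05, the trend recovered 84.5% of 4-fold and 100% of 16-fold changes at 4 h, with 4 and 17 other genes called of 13585. That setting is easier than the real libraries, whose common dispersion was 0.118, so recovery and false calls there may differ. For the 4 h comparison the interval held the true ratio for 98% of 200 unchanged genes and for 94.5% of 200 genes changed 4-fold. Tools were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.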

Results

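Messenger RNA of A549 cells was sequenced at 0.5, 1, 2 and 4 h after transfection of poly-IC, a synthetic double-stranded RNA that sets off the innate antiviral response, and in a mock library treated with transfection reagent alone for 4 h. Double-stranded RNA activates the OAS enzymes, and it also turns on transcription of interferon and other defense genes. Each of the 5 conditions had 1 library, so no difference between conditions has a replicate check, and the intervals below are 95% and cover counting error only. The mock library matched the 4 h library in transfection time, while the 0.5, 1 and 2 h libraries also differed from it in that time.

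GAPDH, a glycolytic enzyme gene, was the most abundant message in the mock, 0.5 h and 1 h libraries, with 2.40%, 2.32% and 2.58% of reads. DUSP1, a phosphatase gene of the immediate early response, led at 2 h with 1.82% (it was named after its values were seen), and the transcription factor gene EGR1 led at 4 h with 2.09%. The 10 most abundant genes took 6.47% of reads in the mock and 10.4% at 4 h.

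The mock and 0.5 h columns were deposited in another form than the other 3, and whether the deposited scale carries the added Drosophila RNA or another scaling is not stated. As deposited, the total was 120090492 in the mock and 13007527 at 4 h, 9.23-fold lower, and the median gene was 4.69-fold lower than mock at 1 h, 8.50-fold at 2 h and 11.7-fold at 4 h. Each of these folds includes the factor of 4 in the form of the mock column, which the 1, 2 and 4 h columns lack. The rest is mainly library size, so these folds do not by themselves show a loss of RNA. In recovered reads the total was 2.31-fold lower at 4 h. Ratios below are scaled by TMM, which centres them on the typical gene, so a gene described as higher was higher relative to other genes. Against TMM, the values as deposited moved the median gene by -0.01, -2.19, -3.04 and -3.48 on the log2 scale in order of time. Total-count scaling moved it by 0.10, 0.20, 0.08 and -0.27.

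The highest ratios at 4 h were of antiviral and inflammatory messages. IFNB1, the beta interferon gene, had 2 reads in the mock and 27426 at 4 h, a ratio of 38119 with an interval from 10551 to 314780. The lambda interferon gene IFNL1 went from 1 to 12830 reads (ratio 35665, 6400 to 1408800), IFNL3 from 1 to 3941 (ratio 10955, 1965 to 432810), and IFNL2 from 0 to 4617, at least 4278-fold. IFIT2, an interferon-stimulated inhibitor of translation, was 12645-fold higher (9591 to 17037), and OASL, a relative of the OAS enzymes, 11469-fold (6409 to 22976). The chemokine gene CXCL8 was 5787-fold higher (4233 to 8139). At the other end, the cell adhesion gene CNTN1 went from 4643 reads to 3, 557-fold lower (190.4 to 2701), and the hydrolase gene CMBL from 1437 to 0.

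In all, 3403 genes were higher and 3272 lower than mock at 4 h, of 13363 compared, by the rule that the whole interval lie beyond 2-fold. With total-count scaling the split was 2880 higher and 4000 lower, and among genes with at least 100 reads 2498 and 3042. In the values as deposited it was 632 higher and 11778 lower. With each count divided by 10, as if 10 reads came from 1 molecule, the rule gave 2166 higher and 1856 lower.

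**Figure D1:**
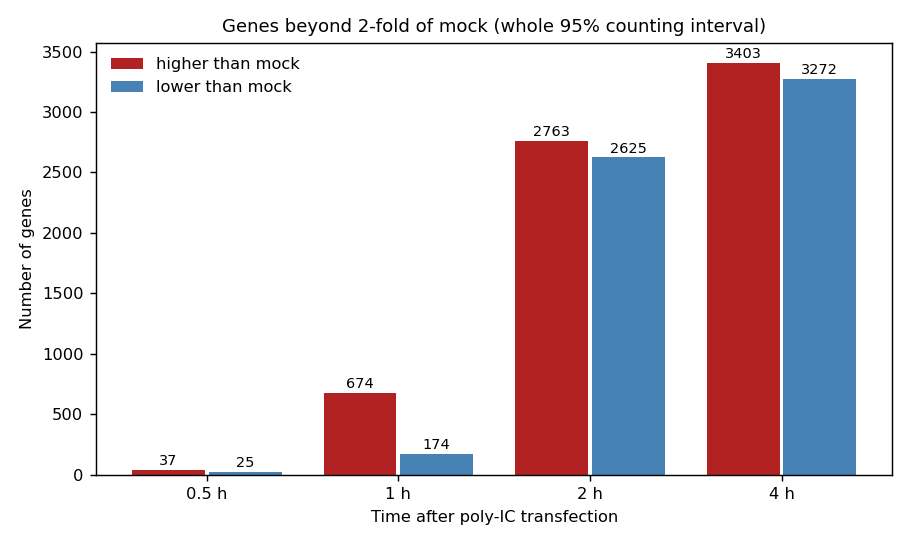
Number of genes (vertical axis) whose whole 95% counting interval of the TMM-scaled ratio to mock lay beyond 2-fold, at each time after poly-IC transfection, red for higher and blue for lower. The bars go from 37 higher and 25 lower genes at 0.5 h to 3403 and 3272 at 4 h, with 1 library per time.

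All 6 interferon genes in the table were higher at 4 h, with a median log2 ratio of 13.69 (percentile 100 of random lists), or 12.74 with genes at 0 reads in the mock set to their bound. Another 15 interferon genes had no row, and every row held a deposited value of at least 32. IFNB1, IFNL1, IFNL2 and IFNL3, with at most 2 reads in the mock, could thus have a row only through a poly-IC library. The direction for these genes was therefore fixed by which rows the table holds. Random lists of like expression had a median of 0.98 (-1.77 to 3.46). Of 59 interferon-stimulated genes 43 were higher and 4 lower, with a median of 3.37 at the 100th percentile of random lists, against -0.10 in the values as deposited. IFIT3 was 3399-fold higher (2611 to 4512), and DHX58, which encodes the RNA sensor LGP2, went from 0 to 2425 reads, at least 2247-fold. MX1, an antiviral GTPase gene, had 46 reads at 2 h and 1225 at 4 h, 681-fold above mock (291 to 2101).

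Among 45 NF-kB and inflammatory genes measured at 4 h, 40 were higher and 0 lower, with a median log2 ratio of 5.35 (percentile 100). The chemokine genes CXCL1 and CCL20 were 5323-fold (2078 to 19542) and 4993-fold (2533 to 11567) higher. CCL5 and CXCL10 had 1 read each in the mock and 7857 and 4159 at 4 h, ratios of 21841 (3919 to 862770) and 11561 (2074 to 456750), and CXCL11 went from 2 to 4626 reads, a ratio of 6430 (1779 to 53107). All 40 immediate early genes, which respond to signals without new protein synthesis, were higher, with a median of 5.18 (percentile 100). EGR1 was 1763-fold higher (1603 to 1943), FOS 653-fold (584 to 733) and EGR3 736-fold (399 to 1536), and EGR4 went from 0 to 903 reads, at least 837-fold.

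The genes of the sensing machinery itself differed widely. Of 27 genes of double-stranded RNA sensing measured at 4 h, 10 were higher and 5 lower, and their median log2 ratio was 0.89, at percentile 99.1, against -2.66 in the values as deposited. The RNA sensor gene IFIH1 was 3624-fold higher (1664 to 9879). OAS2 went from 3 to 7096 reads, 6575-fold (2249 to 31891), while OAS1 was 7.40-fold higher (6.37 to 8.62) and OAS3 5.17-fold (5.02 to 5.32), and in the values as deposited OAS1 and OAS3 were below mock, with log2 ratios of -0.59 and -1.11. TMEM173, which encodes STING, had 0 reads in the mock, 15 at 2 h and 37 at 4 h, at least 34.3-fold higher.

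Of 43 genes of the RNA decay machinery, 4 were higher and 9 lower at 4 h, with a median log2 ratio of -0.13 (percentile 76.7; 0.11 after GC adjustment). ZFP36L2 and ZFP36L1, which encode proteins that bind AU-rich messages, were 13.3-fold (12.8 to 13.9) and 10.96-fold (10.7 to 11.2) higher, with ZFP36L1 at a log2 ratio of -0.021 in the values as deposited. PAN2, which encodes a deadenylase subunit, was 8.88-fold higher (8.20 to 9.63), and at -0.32 on the log2 scale as deposited, while CNOT6L, of another deadenylase, was 10.0-fold lower (7.45 to 13.7).

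Stress and cell death genes were mixed at 4 h. In the integrated stress response list, 11 of 27 genes were higher and 9 lower, with a median log2 ratio of -0.10 (percentile 70.5). PPP1R15A, which encodes a regulator of the phosphatase acting on eIF2alpha, was 455-fold higher (416 to 498), DDIT3, the CHOP gene, 40.5-fold (35.6 to 46.3) and CEBPB 13.7-fold (13.1 to 14.4). GDF15 was 91.6-fold higher at 2 h (74.7 to 113) and 65.7-fold at 4 h (53.5 to 81.6). Of 20 p53 targets 7 were higher and 1 lower, with a median of 0.064 (percentile 80.4, and -0.20 with total-count scaling), and the proapoptotic genes PMAIP1 and BBC3 were 209.9-fold (198 to 222) and 192-fold (152 to 245) higher. TNFRSF10B, a death receptor gene, and PLK3 were 7.90-fold and 7.88-fold higher, and at log2 ratios of -0.49 and -0.50 as deposited.

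At 4 h, of 11 heat shock genes 2 were higher and 5 lower (median log2 ratio -0.79 at percentile 21.1, but -0.20 after GC adjustment and -0.27 over all members with a count), and of 20 chaperones of the endoplasmic reticulum 4 were higher and 6 lower (median -0.088, percentile 72.7). HSP90AA1, HSPA8, HSPD1 and HSPA4L were 5.02-fold, 3.71-fold, 6.03-fold and 8.41-fold lower. PDIA6, PDIA3 and CANX were 15.5-fold, 8.17-fold and 5.25-fold lower, whereas XBP1, a transcription factor gene of the same stress pathway, was 4.52-fold higher (4.35 to 4.70), and at -1.30 on the log2 scale as deposited.

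At 4 h, 11 of 20 housekeeping genes were lower and 2 higher, with a median log2 ratio of -1.67, at percentile 0.05 of random lists. GAPDH was 5.57-fold lower (5.52 to 5.63), ACTB, the beta actin gene, 3.63-fold (3.54 to 3.72) and EEF1A1, an elongation factor gene, 2.04-fold (1.94 to 2.14). The glycolytic genes PGK1 and LDHA were 13.8-fold (12.96 to 14.6) and 11.3-fold (10.96 to 11.7) lower, and TUBA1B, a tubulin gene, 9.70-fold (9.39 to 10.0). B2M, which encodes the light chain of MHC class I, was 14.1-fold higher (13.8 to 14.5). NRF2 targets, genes of the oxidative stress defense, had the lowest median of the lists at 4 h, -2.04 at percentile 0, with 20 of 28 lower and 1 higher. AKR1C1 had 420 reads in the mock, 121 at 2 h and 0 at 4 h. AKR1B10 was 19.2-fold lower (17.3 to 21.3), AKR1C3 16.1-fold (13.8 to 18.9), and ALDH3A1 went from 116 reads to 0.

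Cell cycle genes had a median log2 ratio of -1.05 at 4 h (percentile 0.760), with 18 of 40 lower and 0 higher. TYMS, MCM6, RRM1 and GINS2, genes of DNA synthesis, were 9.73-fold, 7.57-fold, 7.52-fold and 7.06-fold lower. Among the messages with the lowest upper bounds, OIP5, GNG2, CRADD, CDK14, DIRC2 and CCDC109B were at 0 reads at 4 h after 791, 945, 430, 410, 370 and 362 in the mock. HIBCH and REEP1 were at 1 read after 785 and 660, and KDELR3 at 5 after 1351. Among the 1399 genes with 20 to 60 reads at 2 h, 121 were at 0 at 4 h, 11.3 times the mean number at 1, 2 and 3 reads, so no fold is given for genes at 0 in this library.

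The median log2 ratio at 4 h was 0.12 for 79 cytosolic ribosomal protein genes (21 higher, 12 lower, percentile 96.3), but -0.15 with total-count scaling, -0.22 against the 0.5 h library and -3.36 in the values as deposited. It was -0.41 for 75 mitochondrial ribosomal protein genes (4 higher, 17 lower, percentile 24.4), -0.65 for 78 oxidative phosphorylation genes (8 higher, 24 lower, percentile 3.36), -0.70 for 35 proteasome genes (1 higher, 12 lower, percentile 12.0) and -0.56 for 41 translation factors (7 higher, 10 lower, percentile 26.9), all inside the central 95% of random lists. RPS28 was 19.5-fold higher (12.5 to 31.6) and RPL37 8.59-fold (8.07 to 9.14; log2 ratio -0.37 as deposited), and RPL3L went from 0 to 159 reads, while RPL39L was 10.6-fold lower (5.50 to 23.4). EIF4A2 was 9.24-fold higher (8.98 to 9.50; log2 ratio -0.27 as deposited), whereas EIF2B3, EIF3E and EIF3J were 11.9-fold, 5.39-fold and 3.95-fold lower. MRPL19, MRPS35, MRPS10 and MRPS27 were 8.84-fold, 7.52-fold, 5.06-fold and 4.81-fold lower, and the proteasome genes PSMD1, PSMB5, PSMA7 and PSMD14 5.99-fold, 5.18-fold, 4.92-fold and 4.42-fold. Of oxidative phosphorylation genes, NDUFS4, SDHA and ATP5C1 were 8.31-fold, 5.72-fold and 4.91-fold lower, and NDUFA13 6.50-fold higher (4.86 to 8.77; log2 ratio -0.78 as deposited).

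All 38 replication-dependent histone genes, whose transcripts normally end without a poly(A) tail, were higher at 4 h, with a median log2 ratio of 7.57 (percentile 100), or 6.19 with genes at 0 in the mock at their bound. Most of them reached 20 reads only after the mock, and random lists of like expression had a median of 1.85 (0.22 to 3.53). The 8 with at least 20 reads in the mock had a median of 4.52 (3.81 to 6.46, bootstrap). HIST2H2BF went from 1 to 1276 reads, a ratio of 3547 (635 to 140210), HIST4H4 from 0 to 419, HIST2H3D from 0 to 281 and HIST1H3J from 0 to 238. Of 7 nuclear long non-coding RNAs 6 were higher, with a median of 2.69 (percentile 99.9), and of 16 snoRNA host genes 14 were higher, with a median of 2.62 (percentile 100), but in the values as deposited these medians were -0.79 and -0.86. NEAT1, the RNA scaffold of paraspeckles, was 20.3-fold higher (19.96 to 20.6), KCNQ1OT1 25.0-fold (22.2 to 28.3), MIAT 18.4-fold (10.2 to 35.9) and MALAT1 6.45-fold (6.29 to 6.62; log2 ratio -0.79 as deposited). Among snoRNA hosts, SNHG3, SNHG1, SNHG8 and EPB41L4A-AS1 were 26.5-fold, 17.6-fold, 14.5-fold and 10.3-fold higher. KRAB zinc finger genes, a large family of repressors, had a median of 0.95 (percentile 100), with 149 of 365 higher and 23 lower, and of -2.53 in the values as deposited. ZNF501 and ZNF418 went from 0 to 61 and 39 reads, and ZNF792 and ZNF43 from 150 and 109 to 0. The strand setting is not stated, so values of the antisense transcripts KCNQ1OT1 and EPB41L4A-AS1 are uncertain, as are those of near-identical histone copies.

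**Figure D2:**
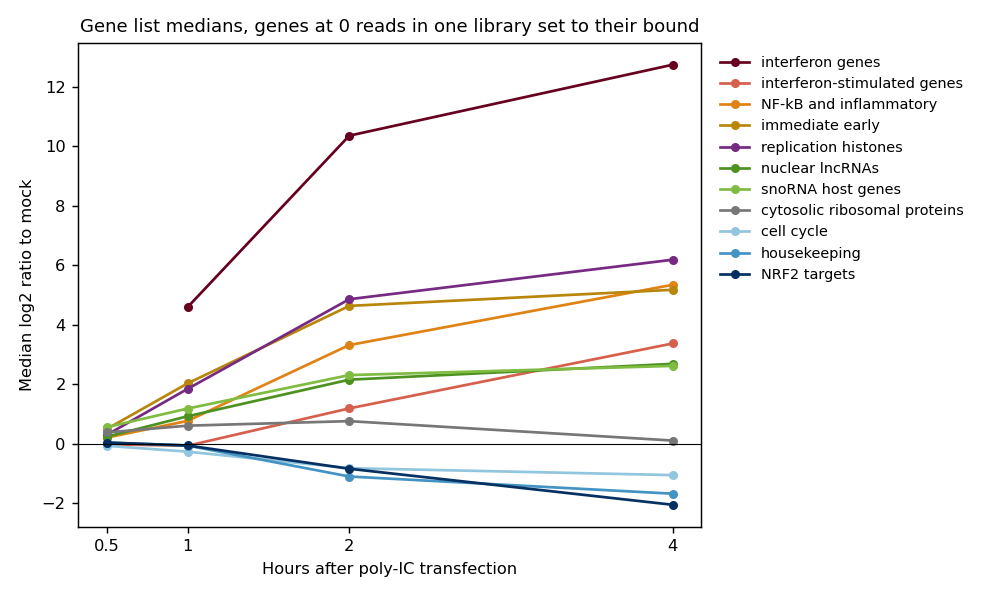
Median log2 ratio to mock (vertical axis, TMM scaling) of 11 gene lists at 0.5, 1, 2 and 4 h after poly-IC (horizontal axis), 1 line per list, with genes at 0 reads in 1 of the 2 libraries set to their bound. Immediate early genes stood at 0.50 at 0.5 h and 5.18 at 4 h, interferon-stimulated genes at -0.012 and 3.38, and NRF2 targets at 0.045 and -2.05. Interferon genes have no point at 0.5 h, where only 1 had enough reads.

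Some transcripts that mark other cell types were also higher at 4 h. Of 4 immune markers with enough reads 3 were higher (median log2 ratio 6.44 at percentile 99.7, or 6.15 at bounds), with CSF1R from 0 to 121 reads, CD14 from 5 to 337, 187-fold (79.5 to 581), and ITGAM from 20 to 324. Another 11 immune markers had no row, and CSF1R and CD14 had enough reads only through the 4 h library. Random lists of like expression had a median of 1.17 (-2.81 to 4.81). CD68 was 1.66-fold above mock (1.47 to 1.87), and at a log2 ratio of -2.75 as deposited. Of 10 fibroblast markers 3 were higher and 2 lower (median 0.35, percentile 39.6), with FAP from 0 to 216 reads, THY1 from 0 to 87, COL1A1 6.15-fold higher (5.94 to 6.37; log2 ratio -0.85 as deposited) and LUM 5.20-fold lower (4.21 to 6.49). The endothelial gene CDH5 went from 0 to 69 reads, and ESAM was at a ratio of 0.933 (0.771 to 1.12). FAP, THY1 and CDH5 also had enough reads only through the 4 h library. The erythroid marker list and the mitochondrially encoded list had 0 members among the rows analysed. Of 13 markers of the line's own epithelial type 4 were higher and 5 lower, with a median of -0.45 (percentile 22.4). ALDH1A1 was 14.1-fold lower (13.6 to 14.6), TFF1 went from 43 reads to 0, and KRT7 and S100P were 6.76-fold (4.98 to 9.30) and 5.86-fold (3.68 to 9.54) higher, with log2 ratios of -0.73 and -0.94 as deposited.

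**Figure D3:**
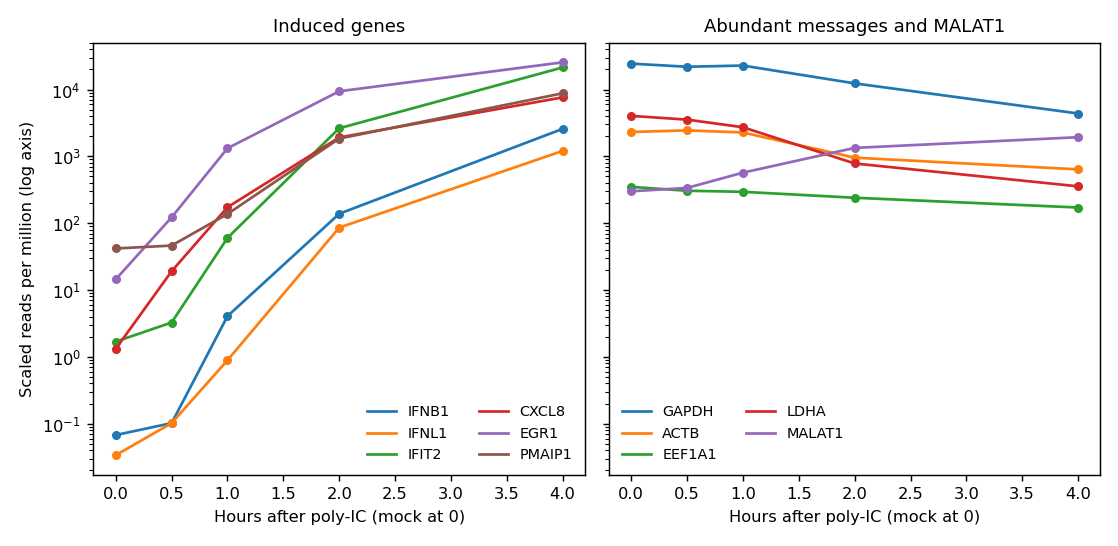
TMM-scaled CPM (vertical log axis) of 11 genes against hours after poly-IC, with the mock library at 0 h and 1 library per point. CXCL8 had 39 reads in the mock and 562 at 0.5 h, whereas IFNB1 had 2 and 3, and 105 at 1 h.

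At 0.5 h CXCL8 was 14.5-fold above mock (10.5 to 20.6), EGR1 8.45-fold (7.65 to 9.37), FOSB 6.29-fold (5.31 to 7.50) and CXCL2 5.96-fold (5.00 to 7.14), and the histone gene HIST3H2A had 45 reads against 0. The lowest were ABCC6P1, CERS4, MACROD2, ELAVL2 and TM4SF20, with 43, 38, 36, 30 and 23 reads in the mock and 3, 3, 2, 2 and 0 at 0.5 h. Immediate early genes had a median log2 ratio of 0.50, snoRNA hosts 0.56 and cytosolic ribosomal proteins 0.38, each at the 100th percentile, and interferon-stimulated genes -0.012 at percentile 58.4. Higher were 4 of 38 immediate early genes, 0 of 15 snoRNA hosts and 0 of 78 ribosomal protein genes. Oxidative phosphorylation (0.25), NF-kB (0.21) and mitochondrial ribosomal lists (0.16) were also at the 100th percentile. Across genes the ratio varied with length (Spearman's rho -0.41) and GC content (0.51), on which random lists were not matched. After GC adjustment the immediate early, snoRNA host and cytosolic ribosomal medians were 0.45, 0.60 and 0.37. Length was not tested. In all, 37 genes were higher and 25 lower, of 12737 compared, or 53 and 23 with total-count scaling, and among genes with at least 100 reads 15 and 0. In the values as deposited they were 177 and 198, and with counts divided by 10 they were 5 and 0.

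At 1 h the highest genes by lower bound were led by CXCL8 and EGR1. CXCL8 stood 131-fold above mock (96.0 to 185), EGR1 91.4-fold (83.1 to 101), FOSB 84.3-fold (72.0 to 99.3), IFIT2 35.6-fold (26.9 to 48.2) and CXCL1 72.1-fold (27.8 to 267), and IFNB1 had 105 reads against 2. Of 39 immediate early genes 34 were higher (median log2 ratio 2.03, percentile 100), while the interferon-stimulated list had a median of -0.062 (percentile 39.8) with 8 of 51 higher. The medians were 4.88 for 4 interferon genes (4.59 at bounds), 1.80 for 20 histones (1.85 at bounds), 1.18 for 16 snoRNA hosts and 0.77 for 37 NF-kB and inflammatory genes, each at the 100th percentile. After GC adjustment these medians were 4.91, 1.91, 1.06 and 0.47. IFNB1, IFNL1 and IFNL2 had enough reads only through the 1 h library. The lowest genes, RAG1, COL5A3, MTMR8, AMACR and WDR63, had 41, 39, 36, 35 and 48 reads in the mock and 0, 0, 0, 0 and 1 at 1 h. In all, 674 genes were higher and 174 lower, of 12889 compared, or 1055 and 71 with total-count scaling, 305 and 55 against the 0.5 h library and 469 and 97 after GC adjustment. In the values as deposited they were 39 and 11863, and with counts divided by 10 they were 163 and 15.

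At 2 h IFNB1 reached 1992 reads, IFIT2 was 1556-fold higher (1180 to 2098), OASL 1436-fold (802 to 2878), CXCL8 1453-fold (1062 to 2043) and EGR1 649.9-fold (591 to 716). The interferon-stimulated list had a median log2 ratio of 1.19 (percentile 100), with 29 of 57 higher and 6 lower, and the immediate early list 4.64 (percentile 100), with 39 of 39 higher. Housekeeping genes had a median of -1.10 (percentile 1.48) and NRF2 targets of -0.82 (percentile 3.47), and GAPDH was 1.97-fold lower (1.96 to 1.98). Cytosolic ribosomal proteins were at 0.76 (percentile 100), against 0.12 at 4 h. OLFML2A had 364 reads in the mock and 1 at 2 h, and LOC100128164, NOMO3, AGMO and APOH went from 204, 187, 162 and 150 reads to 0, while at 4 h OLFML2A and LOC100128164 had 89 and 29 reads. In all, 2763 genes were higher and 2625 lower at 2 h, of 13067 compared. In the values as deposited they were 256 and 11706, and with counts divided by 10 they were 1457 and 1528.

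Over the 5 libraries, 2927 genes rose and 3063 fell with hours of poly-IC, of 13585 tested (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The rises with the smallest adjusted p were of MX1 (2.53 ± 0.11 log2 per hour, SE), PLEKHA4 (2.05 ± 0.094), DLL1 (1.53 ± 0.083), NFKBIE, which encodes an inhibitor of NF-kB (1.30 ± 0.077), and DHRS2 (1.57 ± 0.096), with adjusted p of 0.000473, 0.000473, 0.00103, 0.00119 and 0.00119 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. KCNQ1OT1 (1.22 ± 0.080) tied with NFKBIE and DHRS2 in adjusted p, and ties were ordered by the unadjusted p. The falls with the smallest adjusted p were of CNTN1 (-2.19 ± 0.19), SH3BGRL (-1.43 ± 0.13), FAM81A (-1.40 ± 0.12), PROS1, the gene of protein S (-1.25 ± 0.11), and C7orf73 (-1.05 ± 0.092), with adjusted p of 0.00175, 0.00175, 0.00168, 0.00168 and 0.00175 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. GAPDH, ACTB and EEF1A1 fell, with adjusted p of 0.0235, 0.0183 and 0.0432 in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Total-count scaling gave 1995 rising and 3633 falling genes, and the values as deposited 230 and 8424 (limma-trend). Without the mock library 1668 rose and 1699 fell, and without the 0.5 h library 1778 and 1773. Without the 4 h library 3423 rose and 3654 fell. In that fit, 159 of the genes called in the main fit had a slope of the other sign.

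By list, all 6 interferon genes rose, as did 40 of 59 interferon-stimulated genes, 40 of 45 NF-kB and inflammatory genes, 37 of 40 immediate early genes, 36 of 38 replication histones, 6 of 7 nuclear long non-coding RNAs and 11 of 16 snoRNA hosts, with 0 falling in each of these lists. Adjusted over the list alone, the rises were 6, 41, 40, 40, 37, 6 and 12. IFNB1, IFNL1, IFNL2 and IFNL3 had a row only through poly-IC libraries, so a fall could not have been seen for them. FOSB was 500.4-fold above mock at 2 h and 444-fold at 4 h, and its adjusted p over all genes was 0.0671 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 27 double-stranded RNA sensing genes 12 rose and 4 fell (13 and 4 adjusted over the list alone), and of 367 KRAB zinc fingers 146 rose and 19 fell (146 and 19 adjusted over the list alone).

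Falls outnumbered rises among NRF2 targets (18 of 28 fell, 0 rose), cell cycle genes (21 of 40 fell, 1 rose), housekeeping genes (11 of 20 fell, 2 rose), oxidative phosphorylation (24 of 79 fell, 1 rose), mitochondrial ribosomal proteins (23 of 75 fell, 3 rose), proteasome genes (12 of 35 fell, 1 rose), translation factors (13 of 41 fell, 7 rose) and heat shock genes (4 of 11 fell, 1 rose). Adjusted over the list alone, the falls were 19, 22, 11, 21, 18, 12, 13 and 4, and the rises 0, 1, 2, 1, 3, 1, 7 and 1. Of 79 cytosolic ribosomal protein genes 5 rose and 12 fell, or 3 and 8 adjusted over the list alone.

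In the integrated stress response list 9 of 27 genes rose, PPP1R15A, DDIT3 and CEBPB among them, and 9 fell (10 and 9 adjusted over the list alone). Of 20 p53 targets 6 rose and 1 fell (6 and 1 adjusted over the list alone), of 20 chaperones of the endoplasmic reticulum 4 rose and 5 fell (4 and 5), and of 13 epithelial markers 4 rose and 3 fell (4 and 3). Of 43 RNA decay genes 5 rose and 9 fell (4 and 8 adjusted over the list alone). Among markers of other cells, 3 of 4 immune genes rose and 0 fell, 3 of 10 fibroblast genes rose and 1 fell, and 1 of 2 endothelial genes rose and 0 fell (3 and 0, 3 and 1, and 1 and 0 adjusted over the list alone). A straight line over hours has 3 residual degrees of freedom here, and genes that peaked before 4 h count against it.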

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

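The rule that flagged these 3 genes was applied to named genes only after the same rule on gene lists had flagged nothing. COL5A3 was flagged because it lay on opposite sides of mock at 2 times, at a log2 ratio of -6.11 at 1 h and 2.04 at 4 h, a gap of -8.15, and the difference was not tested. ABCC6P1 was at -3.63 at 0.5 h and 1.66 at 4 h, a gap of -5.29, and the difference was not tested. TFF1 was at 1.81 at 2 h and -4.97 at 4 h, a gap of 6.78, and the difference was not tested. All 3 had low counts, with 39, 43 and 43 reads in the mock, and as COL5A3 had 0 at 1 h and TFF1 0 at 4 h, their values of -6.11 and -4.97, and the gaps, rest on the prior count of 0.5 and are not measured folds.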

How the results depend on the processing

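The values as deposited, counts divided by 10, limma-trend, total-count scaling of the trend and the GC adjustment were chosen after the data were seen. A count of genes stayed the same when within 1.5 times the main count, and a median or ratio when inside its 95% interval. A sign change counted as a reversal only where the main value was called. Here a list median was called outside the central 95% of random lists, and a gene ratio when its interval excluded the mock level. By these rules 511 values stayed the same, 326 moved and 23 reversed. Medians that were not called can change sign inside their interval, as for p53 targets (-0.20 with total-count scaling) and RNA decay (0.11 after GC adjustment). Apart from the values as deposited, the cause was not tested for any that moved.

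All 23 reversals came with the values as deposited. At 4 h these shift the median gene by -3.48 against TMM, so a main value between 0 and that size had to reverse. The shift is made up of the factor of 4 in the mock column and the scaled library sizes, 29559884 in the mock and 10633874 at 4 h. Whether the deposited scale follows amounts of RNA is not stated. The reversals therefore add no measure of amount. Whether the genes and lists named rose or fell in amount stays open. At 4 h the medians were -0.10 for interferon-stimulated genes, -0.86 for snoRNA hosts, -0.79 for nuclear long non-coding RNAs, -2.53 for KRAB zinc fingers and -2.66 for double-stranded RNA sensing. The log2 ratios were ZFP36L1 -0.021, MALAT1 -0.79, OAS3 -1.11, EIF4A2 -0.27, TNFRSF10B -0.49, COL1A1 -0.85, XBP1 -1.30, RPL37 -0.37, PAN2 -0.32, CD68 -2.75, EPB41L4A-AS1 -0.11, OAS1 -0.59, PLK3 -0.50, NDUFA13 -0.78, KRT7 -0.73, ABCC6P1 -1.82, COL5A3 -1.44 and S100P -0.94. The same values moved the medians of NF-kB genes to 1.79, immediate early genes 1.70, integrated stress response -3.58, endoplasmic reticulum chaperones -3.56, heat shock -3.75, p53 targets -3.41, housekeeping -5.14, cytosolic ribosomal proteins -3.36, mitochondrial ribosomal proteins -3.88, oxidative phosphorylation -4.11, histones 4.06, proteasome -4.17, translation factors -4.04, cell cycle -4.52, NRF2 targets -5.52, epithelial markers -3.93, RNA decay -3.60 and fibroblast markers -2.64. Genes higher and lower were 177 and 198 at 0.5 h, 39 and 11863 at 1 h, 256 and 11706 at 2 h, and 632 and 11778 at 4 h, and the trend gave 230 rising and 8424 falling genes. At 0.5 h the shift was only -0.01, and the larger counts of genes there reflect deposited values of about 4 times the reads in both libraries.

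With counts divided by 10, higher and lower genes were 5 and 0 at 0.5 h, 163 and 15 at 1 h, 1457 and 1528 at 2 h, and 2166 and 1856 at 4 h. By point estimate they were 288 and 149 at 0.5 h, and 1350 and 463 at 1 h. With at least 100 counts they were 15 and 0 at 0.5 h, and 114 were lower at 1 h. With no filter 65 were lower at 0.5 h. Against the 0.5 h library, 305 were higher and 55 lower at 1 h, the immediate early median at 4 h was 4.51 and that of cytosolic ribosomal proteins -0.22. With total-count scaling, 1055 were higher and 71 lower at 1 h, and the medians at 4 h were -0.15 for cytosolic ribosomal proteins and 0.68 for KRAB zinc fingers. After GC adjustment 97 genes were lower at 1 h, and the KRAB median was 1.13, that of heat shock genes -0.20 (-0.27 over all members with a count, without the adjustment), and oxidative phosphorylation genes had too few members with a sequence for this adjustment. A prior count of 5 gave a histone median of 5.35. Leaving out 1 library at a time, rising genes ranged from 1668 to 3755 and falling genes from 1699 to 4098. The lowest counts were without the mock library (1668 and 1699), and without the 0.5 h library they were 1778 and 1773.

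No paired analysis was possible because each condition had 1 library. The Drosophila spike-in alternatives, and the spike-in-scaled total of human mRNA, were not run because the table holds 0 Drosophila rows. Depth differed, at 30015691 reads in the mock and 13007527 at 4 h, which limits ratios of genes near 0 reads.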

Other observations

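The tests on histones, on GC content and on the order of the libraries were chosen after the result was seen. A further pair of tests, on the excess of genes at 0 reads, was also written after the result was seen and left the matter undecided, and only its values are given here. Of genes with 20 to 60 reads in the library before, 1 of 1113 was at 0 at 0.5 h, 14 of 1085 at 1 h, 89 of 1096 at 2 h and 121 of 1399 at 4 h. The ratio of genes at 1 to 5 reads to those at 8 to 12 was 0.308, 0.464, 0.632 and 0.455 at 0.5, 1, 2 and 4 h.

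Neighbours within 50 kb of induced genes had a median log2 ratio at 4 h of 1.05 for 27 upstream and 0.06 for 38 downstream ones on the opposite strand, a difference that was not tested. On the same strand, upstream neighbours were at 0.72, percentile 98.0 of random genes of like expression (-0.63 to 0.68), which met the bound for regulation shared across a neighbourhood, while downstream ones, at 0.85 and percentile 97.3, stayed inside their range (-0.62 to 0.86), so sharing stays open. Transcription running past gene ends predicts more on the downstream side, and the difference was 0.13 (-1.01 to 1.47, permutation p = 0.84188, 44 and 44 neighbours), too wide to decide. Among neighbours at least 1 kb away the difference was -0.05 (permutation p = 0.94489, 41 and 42 neighbours). There was no clear difference within 50 kb to remove, and pairs of overlapping genes had been left out of these neighbours. This could therefore not decide on reads shared between overlapping genes, which stay open. Within 10 kb, same-strand neighbours had median log2 ratios at 4 h of 1.44 for 18 downstream and 0.76 for 9 upstream ones. Of these, 9 downstream and 4 upstream ones were over 4-fold. Beyond 10 kb the medians were 0.85 for 26 downstream and 0.68 for 35 upstream ones. The higher downstream median near gene ends was not tested and rests on few neighbours, so transcription running past gene ends stays open.

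All 38 replication histone genes were higher at 4 h. Among members with at least 20 reads in the mock, their median exceeded that of nuclear long non-coding RNAs by 2.38, but the intervals overlapped (3.81 to 6.46 and 0.47 to 4.49), so 1 common rise of all RNA outside the cytoplasm stays open. A difference of 3.50 over all members was set aside, because most histone genes entered through the 4 h library. The cell cycle list had a median of -1.05 (-1.42 to -0.60), which met the bound against more cells in S phase. Housekeeping genes, at -1.67, and NRF2 targets, at -2.04, were lower still on this relative scale. The fall of cell cycle messages thus does not measure the share of cells in S phase, which stays open. Carry-over of RNA without a poly(A) tail stays open, since only RN45S (110.42-fold, 106 to 115) and RPPH1 (1 read in the mock, 869 at 4 h) were measured, under a minimum of 3 that had been lowered to 2 once the result was seen and was then put back. These 2 RNAs lie outside the rule for named genes and were picked for the test after the result was seen.

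Messages rich in the dinucleotides UU and UA were lower at 4 h. Spearman's rho with their density was -0.237 (-0.254 to -0.218) over 10030 genes, and with length -0.124 (-0.144 to -0.106), both past the bound of -0.1 written beforehand, but at -0.028 and -0.055 given GC content. As UU and UA density is nearly GC content (rho -0.96), cleavage and length were set to undecided after these partial values were seen. GC content bias between the libraries could give the pattern, with a rho of 0.616 (0.603 to 0.627) at 1 h, where few genes were beyond 2-fold, against 0.239 at 4 h. The relations with UU and UA density and with length were also stronger before 4 h. At 0.5, 1 and 2 h the rho was -0.524, -0.625 and -0.417 for density, and -0.409, -0.356 and -0.216 for length. Genes are not independent, so these intervals are too narrow.

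For the trend, 1 of 100 orders of the libraries, the real one, gave as many genes as the 5990 found, and the highest other gave 5495. This met the bound against a chance order of the libraries. But of the orders that did not put the 4 h library last the highest gave 52, so the comparison of orders turns mainly on the place of that library. With that library left out, 3423 genes rose and 3654 fell. Of the genes called in the main fit, 1935 rises and 2412 falls were still called then. With 1 library per time, a chance difference of the 4 h library cannot be excluded.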
